A study of Mus musculus with 64 samples.

How the data were processed

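The series held RNA from mouse colon tissue (C57BL/6) in 64 libraries, 41 in a time course after pinch biopsy and 23 in a cohort with 2 arms. Per the labels' protocols, RNA was isolated with RNeasy kits and poly(A) RNA was made into libraries with the TotalScript RNA-Seq kit. Per the submitters' processing notes, reads were aligned to mm10 with STAR and gene levels were computed with Cufflinks, for which the notes give no versions and no annotation. The deposited files held 1 value per gene symbol and library, in FPKM per the labels. Each file was read, its header and units were checked, and the files were joined by symbol, which gave 23997 symbols in the time course, 23995 in the arms and 23990 in both. The total of all FPKM was 414318 to 522098 per library in the time course and 229752 to 266646 in the arms, so the cohorts are on different scales and were tested separately. Read counts are not given in the sources used here, so depth was estimated only in relative terms from the pile-up of values under 0.3 FPKM, and counting precision per gene is unknown. All libraries had Xist of at most 0.0424 FPKM and Ddx3y of at least 4.56 FPKM.

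Samples of the time course were grouped by the condition field of the labels into biopsy and sham at 1 h, 6 h, 3 d and 6 d, and those of the second cohort by their titles into biopsy and sham of the abx-titled and the veh-titled arm. In the arms the titles and the condition field of the labels contradict each other, and the arms are named by title without deciding between them. The labels give no batch and do not say that libraries are from separate animals. Replicate numbers are not consecutive in every group, and no library was left out of the main comparisons.

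Values were taken as log2(FPKM + 1). Genes with at least 1 FPKM in at least 4 libraries of a cohort were tested, 13285 in the time course and 11849 in the arms. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a mean-variance trend, and contrasts gave biopsy against sham, differences of these effects between neighbouring times and between arms, an F test over the sham groups, and the arms' shams and biopsies against each other. P-values were adjusted by the Benjamini-Hochberg method within each comparison, and genes with an adjusted p under 0.05 were called. Residual degrees of freedom were 33 and 19. A total of 31 gene lists of pathways and cell types, with 464 entries of which 458 matched a symbol, were fixed before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with fry and after quantile normalization. Lists with fewer than 3 tested members were not tested, and counts adjusted over the list alone used only the p-values of its members.

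The named genes of a comparison were the 10 largest rises and 10 largest falls among called genes with a log2 change of at least 1, a mean of at least 5 FPKM in the higher group and no overlap between the libraries of the groups. Predicted and unnamed genes, olfactory and similar receptors, small RNAs, immunoglobulin and T cell receptor segments and pseudogenes were passed over. Added to these were up to 4 called members of each described list (up to 2 members where none was called), the 5 largest differences of effect in each direction, and a fixed panel (Il1b, Il6, Cxcl2, Ptgs2, Lgr5, Mki67, Col1a1, Arg1, Reg3b, Reg3g, Car1, Acta2). Some genes that this rule names are not reported here. Coordinates came from GENCODE vM21, where 22652 symbols were matched.

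The alternatives were a pseudocount of 0.1, no filter, a filter of at least 5 FPKM in at least 4 libraries, median of ratios scaling, quantile normalization, array weights, a fit of only the groups compared, replicate number as a block, and leaving out each library in turn. Alternatives chosen after seeing the data were rescaling without small RNA symbols, leaving out libraries rich in B cell genes, and leaving out abx-titled shams 2 and 5. Each comparison was also repeated on 100 splits of its libraries drawn with a fixed seed of 1, the real split included. The fits were tested on simulated data with 200 changed genes, in which 63% to 89% of genes changed by 0.5 and 87% to 100% of genes changed by 1 on the log2 scale were recovered, with 2.84% to 7.5% of the calls false. The simulated noise was normal and independent between genes, without shifts between libraries, and the changed genes were drawn from genes of higher level. These rates check the fits and do not give the error in the real comparisons, where many more genes were called and the split depended on scaling. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables, checks and figures.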

Results

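Messenger RNA was measured by sequencing in 64 libraries of colon tissue from C57BL/6 mice, an inbred laboratory strain, after an injury made by pinch biopsy, in which a small piece of the colonic mucosa is removed with forceps. Per the labels, each library came either from the wound bed of a biopsied colon or from normal tissue after a sham procedure. The time course held 41 libraries, 22 from biopsies and 19 from shams, collected at 1 h (6 biopsies, 4 shams), 6 h (5 and 5), 3 d (6 and 5) and 6 d (5 and 5). A second cohort held 23 libraries collected at 6 h, 11 from biopsies and 12 from shams, in 2 arms meant to compare mice given broad-spectrum antibiotics in their drinking water with mice not given them. The labels of these arms disagree: libraries with abx in the title carry the condition control, and libraries with veh in the title carry the condition of antibiotic treatment. The arms are therefore called abx-titled (5 biopsies, 6 shams) and veh-titled (6 and 6), and no direction with respect to antibiotics is stated.

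The deposited values were FPKM per gene symbol, so total read counts and absolute depth are unknown. Relative depth was estimated from the pile-up of the smallest values and spanned 1.0 to 1.51 in the time course and 1.0 to 1.57 in the arms. The 6 d shams were the shallowest group, with a mean of 1.08 against group means of 1.29 to 1.37 elsewhere in the time course. The number of genes with at least 1 FPKM was 11351 to 12791 per library in the time course and 10442 to 11336 in the arms. Symbols of small RNAs took 5.36% to 24.1% of all FPKM in the time course, with the highest share in a 6 d sham, and 0.07% to 2.33% in the arms. No 2 libraries held identical values, and the correlation of log2 values between libraries was 0.888 to 0.985 in the time course and 0.866 to 0.995 in the arms. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these samples, which may be technical. All changes are differences of log2(FPKM + 1), which understates the change of low genes, with their standard errors (SE), and adjusted p-values are from limma. Genes described outside the lists and the fixed panel were, in comparisons of 2 groups, higher (or lower) in every library of one group than in any library of the other.

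The first question was how the wound bed differed from sham tissue 1 h after injury. Genes switched on within minutes of a stimulus led the response. Fosl1, a subunit of the AP-1 transcription factor, rose from 0.906 ± 0.742 FPKM (SD, n = 4) in shams to 106.5 ± 17.4 FPKM (SD, n = 6) in biopsies, a log2 change of 5.89 ± 0.21 (SE, adjusted p = 4.6e-22). All 20 measured immediate early genes rose (20 adjusted over the list alone), with a median log2 change of 2.06, among them Fosb (5.29), Egr1 (4.30) and Atf3 (3.76). In camera, which asks whether a list changed more than the other genes, this list had an adjusted p = 7.53e-32 and an adjusted p = 7.83e-05 with an estimated correlation. Arc, an activity-regulated gene, rose by 5.32 and Plaur, the urokinase receptor, by 5.12. Sprr1a, a precursor of the cornified envelope that is also induced in injured epithelium, rose from 7.13 ± 4.33 (SD, n = 4) to 408 ± 75.3 FPKM (SD, n = 6).

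Acute cytokines and chemokines also rose at 1 h, in 16 of 18 measured members (18 adjusted over the list alone). They were led by the neutrophil attractant Cxcl1 (5.05), the monocyte attractant Ccl2 (3.92) and Cxcl2 (3.66), and the list had a camera adjusted p = 6.18e-18 and an adjusted p = 0.014 with an estimated correlation. Il6 rose by 3.30, Il1b by 3.14 and Ptgs2, the inducible cyclooxygenase, by 2.48. Of 17 genes of wound-associated epithelium, 13 rose (13 adjusted over the list alone), including the EGF receptor ligands Areg (4.42) and Hbegf (3.85). Genes of wound-associated epithelium had a camera adjusted p = 5.47e-22 and an adjusted p = 0.000116 with an estimated correlation. Of 13 matrix proteases and their regulators, 8 rose and 1 fell (9 and 1 adjusted over the list alone), with Timp1, an inhibitor of metalloproteases, at 1.78 and the aggrecanase Adamts4 at 1.70. Their camera adjusted p was 2.69e-09, with an adjusted p = 0.0211 with an estimated correlation.

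Sterol synthesis genes were a separate group that rose at 1 h. Of 14 members, 12 rose (12 adjusted over the list alone). Insig1, a regulator of sterol sensing, rose by 1.33 and Cyp51, a sterol demethylase, by 1.07. The list had a camera adjusted p = 5.67e-12, but an adjusted p = 0.0921 with an estimated correlation. Of 11 heat shock genes, 8 rose, led by Hspb1 (1.38) and Dnajb1 (1.30), and adjusted over the list alone 8 rose and 1 fell. That list had a camera adjusted p = 1.8e-06 and an adjusted p = 0.136 with an estimated correlation.

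Markers of other cells moved with the injury at 1 h. All 6 measured red blood cell genes rose (6 adjusted over the list alone), with Hba-a1 at 1249 ± 1081 FPKM (SD, n = 6) in biopsies against 45.6 ± 25.3 (SD, n = 4) in shams. Red blood cell genes had a camera adjusted p = 2.07e-08 and an adjusted p = 0.0281 with an estimated correlation. The alpha globin genes Hba-a1 and Hba-a2 and the beta globin genes are near-identical copies, so their separate values are uncertain. Of 15 neutrophil markers, 10 rose (10 adjusted over the list alone), led by the calprotectin subunits S100a9 (4.15) and S100a8 (3.93). Neutrophil markers had a camera adjusted p = 2.69e-08 and an adjusted p = 0.173 with an estimated correlation. Of 7 squamous epithelial markers, 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Krt6a, a keratin of stressed epithelium, at 3.92. Squamous epithelial markers had a camera adjusted p = 4.69e-08 and an adjusted p = 0.00682 with an estimated correlation. Of 17 macrophage markers, 13 fell (14 adjusted over the list alone), among them Csf1r (-1.05) and C1qa (-0.94), at a camera adjusted p = 0.151. After quantile normalization 6 of those 17 fell, and the median shift of all tested genes was -0.18 before it.

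The largest fall at 1 h was in Rnf186, an E3 ubiquitin ligase of the colonic epithelium, from 98.0 ± 33.2 (SD, n = 4) to 9.37 ± 5.10 FPKM (SD, n = 6), a log2 change of -3.31 ± 0.23 (SE, adjusted p = 4.73e-14). The clock output gene Dbp (-2.10), the hedgehog ligand Ihh (-1.63) and the transcription factors Tfap4 (-1.93), Tcf21 (-1.72) and Osr1 (-1.68) fell as well. Col1a1, a chain of type I collagen, fell by 0.76 (adjusted p = 0.013), a call that was lost after median of ratios scaling (adjusted p = 0.00214 to 0.067 over the alternatives). Lgr5, a stem cell marker (-0.20, adjusted p = 0.292), Mki67, a proliferation marker (-0.24, adjusted p = 0.176), Arg1 (-0.10, adjusted p = 0.757), Reg3g (-0.12, adjusted p = 0.75), Car1 (-0.25, adjusted p = 0.313) and Acta2 (0.01, adjusted p = 0.987) did not pass, and Reg3b was too low to be tested in any comparison. A total of 7219 of 13285 tested genes changed (1246 higher and 5973 lower), 301 of them higher and 177 lower by at least 1 on the log2 scale. The split depended on scaling: it was 2796 higher and 2782 lower after median of ratios scaling, and 2054 and 3375 after quantile normalization.

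At 6 h the wound bed was marked by inflammatory genes. S100a9 rose from 0.148 ± 0.198 (SD, n = 5) to 301 ± 124 FPKM (SD, n = 5), a log2 change of 7.96 ± 0.43 (SE, adjusted p = 1.25e-17), and its partner S100a8 rose by 7.43. Il1b, a central inflammatory cytokine, rose from 0.239 ± 0.223 (SD, n = 5) to 192 ± 101 FPKM (SD, n = 5). All 18 cytokines and chemokines rose (18 adjusted over the list alone), with a median log2 change of 4.71 and Cxcl2 (6.90), Ccl4 (6.63), Ccl7 (5.87), Ccl2 (5.85) and Cxcl3 (5.80) among the highest. Their camera adjusted p was 1.03e-15, with an adjusted p = 0.0222 with an estimated correlation. Of 15 neutrophil markers, 14 rose and 1 fell (14 and 1 adjusted over the list alone), among them the decoy receptor Il1r2 (4.47) and the lectin Clec4d (4.35). Neutrophil markers had a camera adjusted p = 2.63e-13 and an adjusted p = 0.0553 with an estimated correlation.

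Interferon-stimulated genes rose at 6 h in 14 of 16 members (14 adjusted over the list alone), with a median log2 change of 2.58. The chemokine Cxcl10 rose from 1.41 ± 1.58 (SD, n = 5) to 118 ± 39.8 FPKM (SD, n = 5), and the antiviral genes Isg15, Ifit1 and Rsad2 rose by 4.89, 4.87 and 4.64. The list had a camera adjusted p = 3.28e-12 and an adjusted p = 0.05 with an estimated correlation, which was not under the threshold, so that call was lost. Il6 rose by 3.37, Ptgs2 by 2.75 and Arg1, the arginine-degrading enzyme of wound macrophages, by 2.84. The red blood cell genes remained higher at 6 h, with all 6 passing (6 adjusted over the list alone), a camera adjusted p = 0.00458 and an adjusted p = 0.339 with an estimated correlation.

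Epithelial genes of wounds rose at 6 h too. Krt6a went from 0.0142 ± 0.0232 (SD, n = 5) to 85.9 ± 25.9 FPKM (SD, n = 5), and 6 of 7 squamous markers rose (6 adjusted over the list alone), with Krt6b, a close copy of Krt6a whose separate value is uncertain, at 4.06, Krt13 at 3.20 and Krt14 at 2.84 (camera adjusted p = 2.6e-06, adjusted p = 0.0222 with an estimated correlation). Of 17 genes of wound-associated epithelium, 15 rose (15 adjusted over the list alone), led by Sprr1a (7.34) and Plet1 (4.29). Genes of wound-associated epithelium had a camera adjusted p = 3.11e-14 and an adjusted p = 0.00513 with an estimated correlation. Of 13 matrix proteases and regulators, 11 rose and 1 fell (11 and 1 adjusted over the list alone), with Timp1 at 5.21 and stromelysin, Mmp3, at 5.20. Matrix proteases and regulators had a camera adjusted p = 1.88e-10 and an adjusted p = 0.0222 with an estimated correlation. The immediate early genes were still raised, 19 of 20 rising (19 adjusted over the list alone) with a median log2 change of 1.08, a camera adjusted p = 1.08e-08 and an adjusted p = 0.0494 with an estimated correlation.

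Single genes of transport and metabolism were among the largest falls at 6 h. Slc37a2, a sugar phosphate transporter, fell from 60.1 ± 29.2 (SD, n = 5) to 7.54 ± 6.05 FPKM (SD, n = 5), a log2 change of -2.99 ± 0.30 (SE, adjusted p = 1e-10), and the alcohol dehydrogenase Adh1 from 1150 ± 135 (SD, n = 5) to 278 ± 111 FPKM (SD, n = 5). Pck1, an enzyme of gluconeogenesis (-2.73), the ion channel Best2 (-2.18) and the monocarboxylate transporter Slc5a8 (-2.02) fell too, as did Nxpe2 (-2.79), Cyp2f2 (-2.35), Hao2 (-2.19) and Selenbp1 (-2.06), the last of which has a close copy, so its value is uncertain. Of 15 genes of fatty acid oxidation and ketogenesis, 11 fell and 2 rose (11 and 2 adjusted over the list alone), with Ppargc1a, a coactivator of mitochondrial genes, at -1.46 and Acaa2, an enzyme of beta-oxidation, at -0.98. Of 13 goblet cell genes, 9 fell and 1 rose (9 and 1 adjusted over the list alone), including their transcription factor Atoh1 (-1.43), and of 16 crypt base and stem cell genes, 10 fell and 2 rose (10 and 3 adjusted over the list alone), including Ascl2 (-1.32) and Lgr5 (-1.10, adjusted p = 1.57e-07). None of these lists passed camera (adjusted p = 0.0996, 0.205 and 0.226). Of 17 colonocyte genes, 5 rose and 4 fell (5 and 4 adjusted over the list alone), with a median log2 change of -0.06, at a camera adjusted p = 0.612. The balance turned with scaling, to 6 rising and 4 falling (median 0.06) after median of ratios scaling and 3 and 6 (median -0.14) after quantile normalization. Col1a1 fell by 1.14 (adjusted p = 0.000181) and Car1, a carbonic anhydrase of surface cells, rose by 0.69 (adjusted p = 0.00286), a call lost after quantile normalization (adjusted p = 0.000106 to 0.0756 over the alternatives). Mki67 (-0.21, adjusted p = 0.208), Reg3g (0.37, adjusted p = 0.283) and Acta2 (-0.24, adjusted p = 0.514) did not pass. A total of 8961 genes changed (3227 higher and 5734 lower), 720 of them higher and 388 lower by at least 1 on the log2 scale, against a median shift of all genes of -0.12. After median of ratios scaling the split was 4259 higher and 4353 lower.

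By 3 d the wound bed showed genes of matrix, macrophages and regenerating epithelium. Krt14, a keratin of basal squamous cells, rose from 1.37 ± 0.196 (SD, n = 5) to 61.4 ± 26.2 FPKM (SD, n = 6), a log2 change of 4.61 ± 0.21 (SE, adjusted p = 7.1e-19). Arg1 rose from 0.0932 ± 0.0405 (SD, n = 5) to 24.3 ± 8.23 FPKM (SD, n = 6), and Spp1, the secreted phosphoprotein osteopontin, by 4.24. Clu, the secreted chaperone clusterin (4.30), Timp1 (4.26) and Retnlb, a goblet cell protein induced in inflammation (4.25), were among the genes with the largest rise, together with S100a9 (4.25), Il1b (4.23), Cxcl2 (4.04) and S100a8 (4.04). All 13 matrix proteases and regulators rose (13 adjusted over the list alone), among them Timp1 and Mmp10 (2.63). Matrix proteases and regulators had a camera adjusted p = 8.73e-12 and an adjusted p = 0.0248 with an estimated correlation. Of 17 genes of wound-associated epithelium, 15 rose (15 adjusted over the list alone), with the claudin Cldn4 and Sprr1a both at 2.62. Genes of wound-associated epithelium had a camera adjusted p = 2.08e-09 and an adjusted p = 0.025 with an estimated correlation.

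Of 20 collagen and matrix genes, 15 rose at 3 d and none fell (15 adjusted over the list alone). Col1a1 rose from 24.0 ± 8.98 (SD, n = 5) to 98.1 ± 44.1 FPKM (SD, n = 6), and Lox, which crosslinks collagen, rose by 2.37. The list had a camera adjusted p = 2.39e-06 and an adjusted p = 0.423 with an estimated correlation. Of 17 macrophage markers, 15 rose (16 adjusted over the list alone), including the chemokine receptor Ccr2 (1.15) and the complement subunit C1qb (0.99). Macrophage markers had a camera adjusted p = 2.64e-05 and an adjusted p = 0.37 with an estimated correlation. Of 13 endothelial genes, 10 rose (12 adjusted over the list alone), with Egfl7 at 1.22 and Selp, P-selectin, at 1.19. Endothelial genes had a camera adjusted p = 0.00387 and an adjusted p = 0.566 with an estimated correlation. Of 20 cell cycle genes, 13 rose (16 adjusted over the list alone), among them Rrm2 (1.15) and Mcm3 (0.79), while Mki67 was at -0.02 (adjusted p = 0.935). Their camera adjusted p was 0.024, with an adjusted p = 0.706 with an estimated correlation.

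Inflammatory genes remained higher at 3 d. All 18 cytokines and chemokines rose (18 adjusted over the list alone), with a median log2 change of 1.89. Cytokines and chemokines had a camera adjusted p = 1.45e-08 and an adjusted p = 0.279 with an estimated correlation. After quantile normalization 14 of them rose, and Il6 (0.60, adjusted p = 0.0315) was among those no longer called (adjusted p = 2.71e-07 to 0.184 over the alternatives). Of 15 neutrophil markers, 14 rose (14 adjusted over the list alone), with a camera adjusted p = 3.78e-06 and an adjusted p = 0.37 with an estimated correlation. Of 7 squamous markers, 4 rose (4 adjusted over the list alone), with Krt14 and Krt13 (3.01) above Krt6a (0.66) and Krt15 (0.65). Squamous markers had a camera adjusted p = 0.0141 and an adjusted p = 0.37 with an estimated correlation. Ptgs2 rose by 1.40 (adjusted p = 0.000322) and Lgr5 by 0.49 (adjusted p = 0.00825), which was not called when only the 3 d groups were fitted or without sham 3 d replicate 1 (adjusted p = 0.000384 to 0.0717 over the alternatives). Reg3g was at 0.40 (adjusted p = 0.27).

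Smooth muscle genes and some surface colonocyte genes fell at 3 d. Of 13 smooth muscle genes, 12 fell (12 adjusted over the list alone), with the muscle myosin Myh11 going from 202 ± 80.2 (SD, n = 5) to 54.1 ± 27.8 FPKM (SD, n = 6) and Acta2, smooth muscle actin, at -0.99 (adjusted p = 0.00883). The list had a camera adjusted p = 1.55e-07 and an adjusted p = 0.37 with an estimated correlation. Of 17 colonocyte genes, 7 fell and 3 rose (7 and 3 adjusted over the list alone). Colonocyte genes had a camera adjusted p = 0.000656 and an adjusted p = 0.37 with an estimated correlation. Slc26a3, the chloride and bicarbonate exchanger of surface cells, fell from 615 ± 188 (SD, n = 5) to 161 ± 28.8 FPKM (SD, n = 6), a log2 change of -1.90 ± 0.16 (SE, adjusted p = 1.46e-11), and the water channel Aqp8 (-1.41) and Car1 (-1.32, adjusted p = 1.18e-06) fell as well. Other large falls were in Pcp4 (-2.84), the pentraxins Mptx1 (-2.24) and Mptx2 (-2.06), which are near copies and so uncertain, and the muscle genes Ckm (-2.08) and Tnnt2 (-1.66). A total of 5666 genes changed (4269 higher and 1397 lower), 336 of them higher and 80 lower by at least 1 on the log2 scale. The split was 2617 higher and 2708 lower after median of ratios scaling, 2538 and 3282 after quantile normalization, and 3237 and 1916 when libraries were rescaled without small RNAs, a scaling chosen after seeing the data.

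At 6 d the wound bed was marked by osteopontin, collagens and a goblet cell product. Spp1 rose from 0.0612 ± 0.0322 (SD, n = 5) to 23.8 ± 8.51 FPKM (SD, n = 5), a log2 change of 4.48 ± 0.23 (SE, adjusted p = 3.15e-17), and Retnlb from 0.309 ± 0.270 (SD, n = 5) to 18.3 ± 2.04 FPKM (SD, n = 5). Of 20 collagen and matrix genes, 18 rose (19 adjusted over the list alone), and Col1a1 rose from 33.3 ± 4.20 (SD, n = 5) to 224 ± 71.9 FPKM (SD, n = 5), with Lox at 2.58 and Col1a2 at 2.03. The list had a camera adjusted p = 7.53e-09 and an adjusted p = 0.377 with an estimated correlation. Of 13 matrix proteases and regulators, 12 rose (12 adjusted over the list alone), with Timp1 at 3.25 and the collagenase Mmp13 at 2.61. Matrix proteases and regulators had a camera adjusted p = 1.06e-10 and an adjusted p = 0.0399 with an estimated correlation. Krt14 (3.86), the secreted proteins Wfdc18 (3.87) and Hp, haptoglobin (3.61), the proteases Klk15 (3.78) and Prss22 (3.41), the retinoic acid synthesizing enzyme Aldh1a3 (3.44) and Clu (3.35) were also among the largest rises.

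Of 17 surface colonocyte genes, 13 fell and 2 rose at 6 d (13 and 2 adjusted over the list alone). Car4, a carbonic anhydrase, fell from 1278 ± 76.3 (SD, n = 5) to 297 ± 81.9 FPKM (SD, n = 5), Slc26a3 fell by 2.28 and Aqp8 by 2.05, and the list had a camera adjusted p = 1.65e-09 and an adjusted p = 0.0659 with an estimated correlation. Of 13 smooth muscle genes, 7 fell (9 adjusted over the list alone), with a camera adjusted p = 3.86e-05 and an adjusted p = 0.525 with an estimated correlation, while Acta2 was at -0.56 (adjusted p = 0.15). Of 13 goblet cell genes, 8 rose and 1 fell (8 and 1 adjusted over the list alone), among them Spink4 (1.84), Clca1 (1.23) and the mucin Muc2 (0.85). Goblet cell genes had a camera adjusted p = 0.0147 and an adjusted p = 0.547 with an estimated correlation. Of 20 cell cycle genes, 15 rose (15 adjusted over the list alone), with a camera adjusted p = 0.00365 and an adjusted p = 0.605 with an estimated correlation. Mki67, at 0.42 (adjusted p = 0.0219), was not called after median of ratios scaling or quantile normalization (adjusted p = 0.00508 to 0.102 over the alternatives).

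Inflammatory and wound genes had not returned to the sham level at 6 d. Of 18 cytokines and chemokines, 15 rose (17 adjusted over the list alone), with Cxcl5 at 3.25, Il1b at 3.11 and Cxcl2 at 2.45. Cytokines and chemokines had a camera adjusted p = 8.06e-05 and an adjusted p = 0.377 with an estimated correlation. After median of ratios scaling, and likewise after quantile normalization, 12 of them rose. Of 15 neutrophil markers, 12 rose (14 adjusted over the list alone), with S100a9 at 3.68. Neutrophil markers had a camera adjusted p = 0.000583 and an adjusted p = 0.525 with an estimated correlation. Of 17 wound-associated epithelial genes, 13 rose (14 adjusted over the list alone), with a camera adjusted p = 4.66e-05 and an adjusted p = 0.172 with an estimated correlation. Il6 (1.11, adjusted p = 0.000285), Ptgs2 (1.03, adjusted p = 0.00833), Arg1 (3.25) and Lgr5 (0.55, adjusted p = 0.00497) were higher, and Reg3g was at 0.05 (adjusted p = 0.907).

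Interferon-stimulated genes were lower in biopsies than in shams at 6 d. Of 16 members, 9 fell and 2 rose (9 and 2 adjusted over the list alone), led by Oasl2 (-1.62), Ifit1 (-1.48), Irf7 (-1.28) and Isg15 (-1.27). The interferon list had a camera adjusted p = 7.45e-05 and an adjusted p = 0.377 with an estimated correlation. Ifit1 was 7.35 ± 3.15 FPKM (SD, n = 5) in biopsies and 23.9 ± 16.1 (SD, n = 5) in shams of 6 d, while the shams of 1 h, 6 h and 3 d held 0.848 ± 0.193 (SD, n = 4), 1.85 ± 1.52 (SD, n = 5) and 0.921 ± 0.346 FPKM (SD, n = 5). The 6 d shams were also the shallowest group and had the highest small RNA share, up to 24.1%. The largest falls at 6 d were in Retnla, a marker of alternatively activated macrophages (-3.20, adjusted p = 7.67e-06), Hba-a2 (-2.30, a globin with a near-identical copy), Slc26a3 and Car4 (-2.14), followed by Dbp (-2.14), Aqp8, Pcp4 (-2.04) and the deubiquitinase Usp2 (-1.99). A total of 5875 genes changed (4524 higher and 1351 lower), 297 of them higher and 98 lower by at least 1 on the log2 scale, against a median shift of all genes of 0.11. The split was 2473 higher and 2372 lower after median of ratios scaling and 2456 and 2768 after quantile normalization, and 5126 genes were called without the libraries rich in B cell genes, biopsy replicate 3 and sham replicate 2, an alternative chosen after seeing the data.

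**Figure D1:**
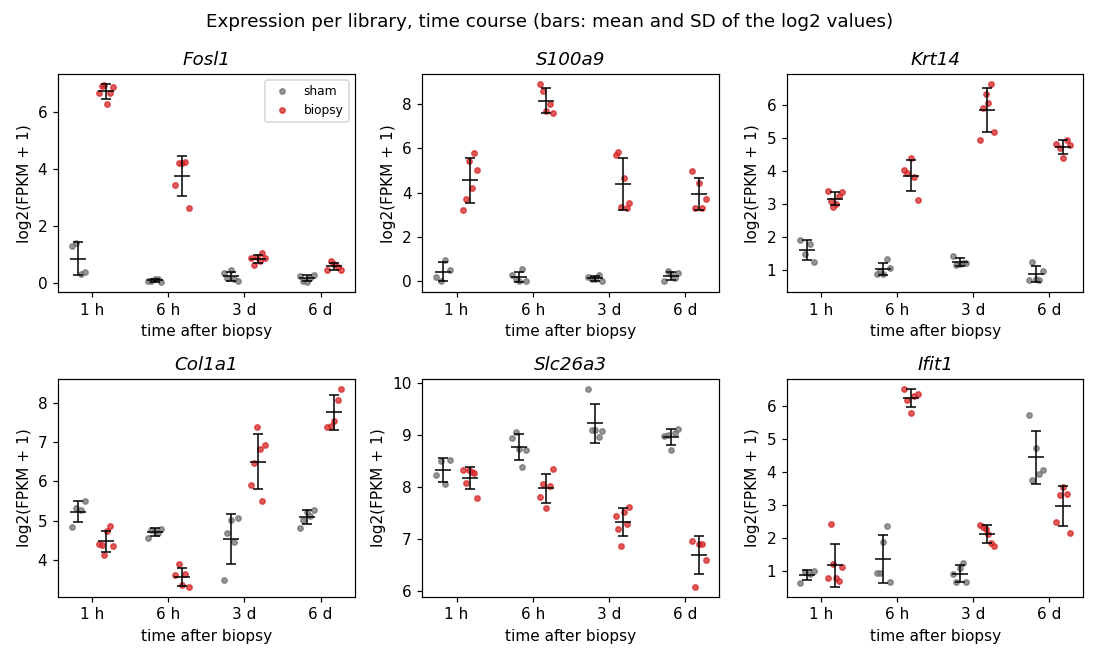
Each point is 1 library of the time course, with sham in grey and biopsy in red by time after injury on the horizontal axis, the vertical axis is log2(FPKM + 1), and the bars are the mean and SD of the log2 values of each group. Krt14 in the 11 biopsies of 3 d and 6 d, at 19.9 FPKM or more, lay above the highest of the 10 shams, 1.71 FPKM, and Ifit1 was raised in the 6 d shams.

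**Figure D2:**
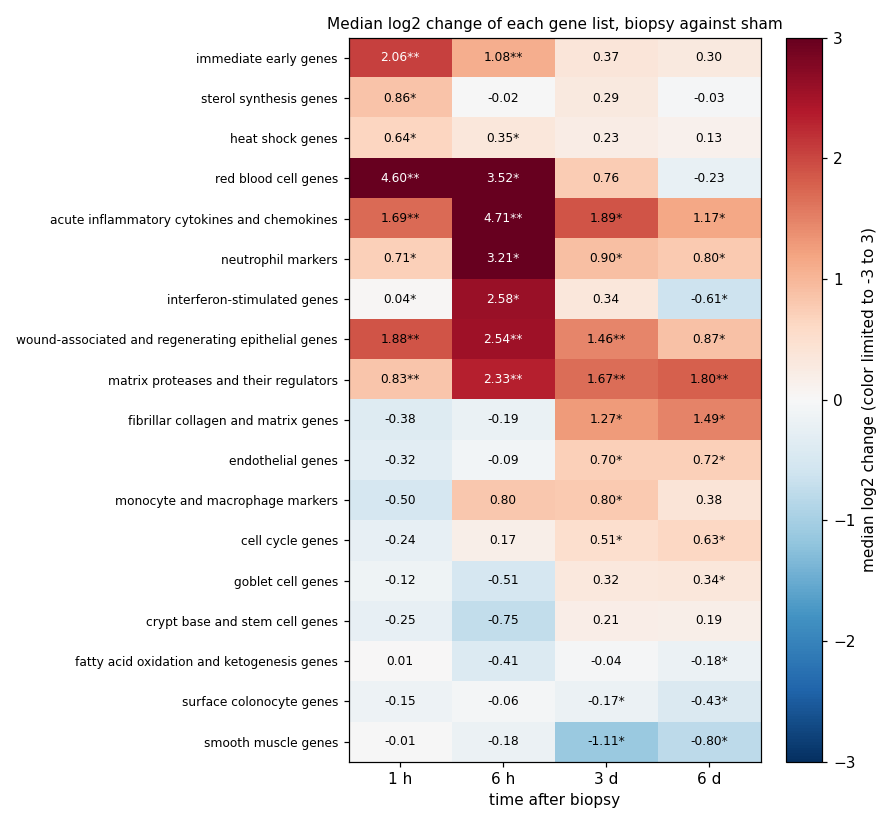
Colors give the median log2 change between biopsy and sham over the tested members of 18 gene lists at the 4 times, limited to -3 to 3. One star marks lists with a camera adjusted p under 0.05 and a pair of stars those that also passed with an estimated correlation; cytokines went from 1.69 at 1 h to 4.71 at 6 h, 1.89 at 3 d and 1.17 at 6 d.

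Whether the effect of the biopsy differed between neighbouring times was tested directly. Between 1 h and 6 h, the largest upward differences were in the chemokines Cxcl3 (difference of 4.97 ± 0.52, SE, adjusted p = 2.26e-09), and Ccl4 (4.85), the interferon-stimulated Ifit3 (4.73) and Ifit1 (4.58), and stromelysin, Mmp3 (4.51). Of 18 cytokines and chemokines, 12 had a larger effect at 6 h (12 adjusted over the list alone; camera adjusted p = 0.000475, adjusted p = 0.536 with an estimated correlation). Of 16 interferon-stimulated genes, 14 had a larger effect at 6 h (14 adjusted over the list alone). Interferon-stimulated genes had a camera adjusted p = 4.68e-09 and an adjusted p = 0.362 with an estimated correlation. Neutrophil markers did so in 14 of 15 members (adjusted over the list alone, 14 larger and 1 smaller), with a camera adjusted p = 7.04e-08 and an adjusted p = 0.451 with an estimated correlation. The effect on Arc (-3.92), Fosb (-3.48) and Atf3 (-2.76) was smaller at 6 h, and that on Pck1 (-3.34) and Slc37a2 (-2.95) was lower. Of 20 immediate early genes, 13 had a smaller effect (13 adjusted over the list alone; camera adjusted p = 3.59e-06, adjusted p = 0.362 with an estimated correlation), as did 11 of 14 sterol synthesis genes (12 adjusted over the list alone; camera adjusted p = 2.82e-07, adjusted p = 0.451 with an estimated correlation), with Insig1 at -1.79. The effect differed for 6226 genes (3991 upward and 2235 downward), with a split of 3262 and 2958 after median of ratios scaling and 2920 and 3408 after quantile normalization.

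Between 6 h and 3 d the effect on inflammatory genes and matrix proteases declined and that on collagen and matrix genes rose. The difference was -5.71 ± 0.24 (SE, adjusted p = 3.43e-19) for Krt6a, -5.04 for Cxcl10, -4.72 for Sprr1a, -4.39 for Ifit3 and -4.36 for Rsad2. The interferon list was lower in 14 of 16 members (14 adjusted over the list alone; camera adjusted p = 2.01e-17, adjusted p = 0.0303 with an estimated correlation), and cytokines in 15 of 18 (16 adjusted over the list alone; camera adjusted p = 1.24e-14, adjusted p = 0.0445 with an estimated correlation). Of 15 neutrophil markers, 14 were lower and 1 higher (14 and 1 adjusted over the list alone). Neutrophil markers had a camera adjusted p = 1.17e-14 and an adjusted p = 0.0445 with an estimated correlation. Upward differences were led by Clu (4.05 ± 0.81, SE, adjusted p = 9.86e-05), Retnlb (3.41), Klk15 (3.33), Col1a1 (3.09) and Nov, a secreted matricellular protein (2.90). Collagen and matrix genes were higher in 15 of 20 members and lower in 2 (16 and 2 adjusted over the list alone), with a camera adjusted p = 0.0181 and an adjusted p = 0.732 with an estimated correlation, and goblet cell genes in 11 of 13 (11 adjusted over the list alone; 7 after median of ratios scaling), with a camera adjusted p = 0.00942 and an adjusted p = 0.525 with an estimated correlation. Of 13 matrix proteases and regulators, 9 had a lower and 2 a higher effect (9 and 2 adjusted over the list alone; camera adjusted p = 3.7e-05, adjusted p = 0.131 with an estimated correlation), with Mmp3 at -3.48 and Mmp2 at 1.59. Smooth muscle genes had a lower effect in 6 of 13 members (6 adjusted over the list alone; camera adjusted p = 0.00029, adjusted p = 0.525 with an estimated correlation). The effect differed for 6936 genes (5475 upward and 1461 downward) while the median of all genes moved by 0.19, with a split of 2604 and 2992 after median of ratios scaling and 3277 and 2341 after quantile normalization.

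Between 3 d and 6 d few genes differed in their response. The secreted protein C1qtnf3 (2.03 ± 0.41, SE, adjusted p = 0.00603), the matrix protein Fmod, fibromodulin (2.01, adjusted p = 6.25e-05), and Mfap4, a protein of elastic fibers (1.34), together with the growth factor Mdk (1.28) and Mal (1.35), had a higher effect at 6 d. Interferon-stimulated genes had a lower one, with Oasl2 at -2.81 ± 0.45 (SE, adjusted p = 0.000326), Ifit1 at -2.68, Isg15 at -2.58 and the near-identical pair Apol9a (-2.52) and Apol9b (-2.34), which are uncertain. The interferon list was lower in 7 of 16 members (9 adjusted over the list alone), with a camera adjusted p = 7.35e-11 and an adjusted p = 0.157 with an estimated correlation. The level of these genes was raised in the 6 d shams. The effect differed for 244 genes (109 upward and 135 downward), with 176 and 92 when libraries were rescaled without small RNAs, a scaling chosen after seeing the data. The count moved with single libraries, to 521 without sham 3 d replicate 1, 159 without sham 3 d replicate 2, 146 without biopsy 6 d replicate 2 and 155 without sham 6 d replicate 1, and was 1006 with array weights, 161 when only these groups were fitted and 131 with a replicate block.

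Across all 13285 tested genes, which are not independent replicates, the correlation of log2 changes was 0.511 between 1 h and 6 h, 0.561 between 6 h and 3 d and 0.736 between 3 d and 6 d. It was 0.226 between 1 h and 3 d, 0.135 between 1 h and 6 d and 0.361 between 6 h and 6 d. No library was shared between times. Of the genes higher in biopsies at 3 d, 3038 were also higher at 6 d, where independent lists of these sizes would share 1454. Of those lower, 773 were also lower, against 142. For 1 h and 6 h the shared genes were 888 higher, against 303, and 3638 lower, against 2578. For 6 h and 3 d they were 2125 higher and 1122 lower, against 1037 and 603. In opposite directions, 72 genes were higher at 1 h and lower at 6 h, and 620 the reverse. These were 39 and 748 between 6 h and 3 d, and 27 and 16 between 3 d and 6 d. All these counts are from the main fits, and the split at each time depended on scaling.

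Sham tissue itself differed between collection times, which is the background of each comparison. The smallest p-values in a limma F test over the 4 sham groups belonged to Dtx3l (adjusted p = 3.27e-13), Parp9 (7.29e-13), Stat2 (1.53e-12), Dohh (1.53e-12) and Parp14 (2.56e-12), of which Stat2 is a transducer of interferon signals and Dtx3l, Parp9 and Parp14 are interferon-induced. Dtx3l was at 5.29 ± 1.16 (SD, n = 4), 8.26 ± 0.527, 10.9 ± 1.17 and 27.0 ± 4.47 FPKM (SD, n = 5 each) in the shams of 1 h, 6 h, 3 d and 6 d. All 16 interferon-stimulated genes of the list were higher in the 6 d shams than in the 14 shams of the other times, with a median log2 difference of 2.06, in a contrast chosen after seeing the data. A total of 7835 genes differed among the sham groups, and 6851 did without the libraries rich in B cell genes.

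In the second cohort, the question was how the response to injury at 6 h depended on antibiotics, and each arm was first compared with its own shams. In the abx-titled arm Sprr1a rose from 1.20 ± 0.605 (SD, n = 6) to 527 ± 120 FPKM (SD, n = 5), a log2 change of 7.91 ± 0.18 (SE, adjusted p = 1.26e-18), followed by S100a9 (7.05), S100a8 (6.75), Krt6a (5.78), Ccl2 (5.55) and Il1b (5.42). All 20 cytokines and chemokines rose (20 adjusted over the list alone), with a median log2 change of 2.85. Cytokines and chemokines had a camera adjusted p = 2.14e-13 and an adjusted p = 0.0478 with an estimated correlation. Of 16 genes of wound-associated epithelium, 15 rose (15 adjusted over the list alone; camera adjusted p = 1.21e-12, adjusted p = 0.0249 with an estimated correlation), and of 13 matrix proteases and regulators, 12 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 2e-08, adjusted p = 0.0478 with an estimated correlation), with Mmp3 at 5.08. Of 14 neutrophil markers, 13 rose (13 adjusted over the list alone; camera adjusted p = 7.6e-09, adjusted p = 0.215 with an estimated correlation), and of 7 squamous markers 5 rose (5 adjusted over the list alone; camera adjusted p = 8.46e-05, adjusted p = 0.0478 with an estimated correlation). All 6 red blood cell genes rose (6 adjusted over the list alone; camera adjusted p = 0.00144, adjusted p = 0.314 with an estimated correlation). All 8 enteric nerve genes rose as well (8 adjusted over the list alone), with the neuropeptide Vip at 2.05 and the glial Gfap at 1.68. Enteric nerve genes had a camera adjusted p = 0.00567 and an adjusted p = 0.575 with an estimated correlation.

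The largest falls in the abx-titled arm were in single genes. The proton pump Atp12a fell by 2.99, Slc37a2 by 2.89, Pck1 by 2.88 and Best2 by 2.72, and Adh1 went from 611 ± 142 (SD, n = 6) to 82.8 ± 16.0 FPKM (SD, n = 5). Selenbp1 (-2.85) and Selenbp2 (-2.68) are close copies and uncertain. Of 16 colonocyte genes, 5 fell and 2 rose (4 and 2 adjusted over the list alone), at a camera adjusted p = 0.991. Of 15 genes of fatty acid oxidation and ketogenesis, 9 fell and 3 rose (9 and 3 adjusted over the list alone), at a camera adjusted p = 0.338. Il6 (2.95), Ptgs2 (2.04) and Arg1 (1.80) rose and Col1a1 fell by 1.31, while Mki67 (-0.27, adjusted p = 0.213), Car1 (-0.09, adjusted p = 0.847) and Acta2 (-0.56, adjusted p = 0.255) did not pass. Lgr5 and Reg3g were below the filter in this cohort. A total of 8350 of 11849 tested genes changed (3144 higher and 5206 lower), 666 of them higher and 570 lower by at least 1 on the log2 scale, against a median shift of all genes of -0.12. The split was 4052 higher and 4182 lower after median of ratios scaling, and 5346 genes changed with a stricter filter of at least 5 FPKM, which left 7316 genes to test.

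In the veh-titled arm the same comparison gave a rise of Sprr1a from 0.951 ± 0.402 (SD, n = 6) to 455 ± 82.7 FPKM (SD, n = 6), a log2 change of 7.88 ± 0.17 (SE, adjusted p = 2.74e-19). S100a9 (7.30), S100a8 (6.96), Cxcl2 (6.83), Il1b (6.54), Krt6a (6.26), Ccl4 (6.19), Cxcl1 (6.08), Ccl2 (5.73) and Ccl3 (5.60) followed. All 20 cytokines and chemokines rose (20 adjusted over the list alone), with a median log2 change of 3.48. Cytokines and chemokines had a camera adjusted p = 5.66e-16 and an adjusted p = 0.0285 with an estimated correlation. Wound-associated epithelial genes rose in 15 of 16 members (15 adjusted over the list alone; camera adjusted p = 9.03e-13, adjusted p = 0.0237 with an estimated correlation), and matrix proteases in 11 of 13 with 1 fall (12 and 1 adjusted over the list alone; camera adjusted p = 6.96e-08, adjusted p = 0.0417 with an estimated correlation). Neutrophil markers rose in 13 of 14 (13 adjusted over the list alone; camera adjusted p = 3.89e-09, adjusted p = 0.2 with an estimated correlation), and squamous markers in 6 of 7 (6 adjusted over the list alone; camera adjusted p = 4.58e-06, adjusted p = 0.0285 with an estimated correlation). Red blood cell genes rose in 5 of 6 (5 adjusted over the list alone; camera adjusted p = 0.011, adjusted p = 0.478 with an estimated correlation). Of 8 enteric nerve genes, 2 rose (1 adjusted over the list alone), at a camera adjusted p = 0.302.

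Among the genes that fell in the veh-titled arm were Pck1 (-3.34), Slc37a2 (-3.25), Rnf186 (-2.69), Best2 (-2.69), the pyruvate dehydrogenase kinase Pdk2 (-2.63), Slc5a8 (-2.45) and the translation inhibitor Pdcd4 (-2.43). Adh1 went from 644 ± 62.6 (SD, n = 6) to 111 ± 19.3 FPKM (SD, n = 6). Sprr2a2, one of several near-identical copies, was listed at 0 in 5 of the 6 biopsies and at 667 FPKM in the other, and is uncertain. Il6 (3.56), Ptgs2 (2.73) and Arg1 (1.34) rose, Col1a1 (-1.80) and Acta2 (-1.18, adjusted p = 0.0136) fell, and Car1 was at -0.10 (adjusted p = 0.809). Mki67, at -0.44 (adjusted p = 0.0343), was not called after median of ratios scaling or quantile normalization (adjusted p = 0.00459 to 0.17 over the alternatives). A total of 8848 genes changed (3040 higher and 5808 lower), 673 of them higher and 758 lower by at least 1 on the log2 scale, against a median shift of all genes of -0.17. The split was 4235 higher and 4351 lower after median of ratios scaling and 3868 and 4836 after quantile normalization, and 5605 genes changed with the stricter filter.

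Whether the arms differed in their response was tested as the difference of both effects. Some cytokines and chemokines had a lower effect in the abx-titled arm. The difference was -2.10 ± 0.41 (SE, adjusted p = 0.00658) for Il1a, -2.05 (adjusted p = 0.0116) for Ccl3, -1.52 (adjusted p = 0.01) for Cxcl2, -1.44 (adjusted p = 0.0478) for Ccl4 and -1.33 (adjusted p = 0.00966) for Csf3, the granulocyte colony stimulating factor. In biopsies, Il1a was at 1.88 ± 1.5 FPKM (SD, n = 5) in the abx-titled and 11.2 ± 6.60 (SD, n = 6) in the veh-titled arm, and Cxcl2 at 42.1 ± 18.9 (SD, n = 5) and 125 ± 60.8 FPKM (SD, n = 6). Of 20 cytokines and chemokines, 6 had a lower effect and none a higher one (9 lower adjusted over the list alone). Cytokines and chemokines had a camera adjusted p = 7.42e-10 and an adjusted p = 0.218 with an estimated correlation. Of 7 squamous markers, 2 had a lower effect (5 adjusted over the list alone), Krt13 at -1.18 and Krt14 at -0.65. Squamous markers had a camera adjusted p = 9.06e-06 and an adjusted p = 0.0792 with an estimated correlation. Some alternatives lost the calls of Ccl3 (adjusted p = 0.004 to 0.0512), Ccl4 (0.021 to 0.0758) and Krt14 (0.019 to 0.282).

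The effect was higher in the abx-titled arm for Id3, an inhibitor of helix-loop-helix transcription factors (1.16 ± 0.18, SE, adjusted p = 0.00195), Erbb3, a receptor of the EGF family (1.06), the collagen chain Col6a2 (0.99), Clca6 (0.98) and Igfbp3 (0.97). Some alternatives lost the calls of Erbb3 (adjusted p = 0.0106 to 0.0741) and Clca6 (0.0158 to 0.0805). Of 18 collagen and matrix genes, 4 had a higher effect (8 adjusted over the list alone), with a camera adjusted p = 3.68e-06 and an adjusted p = 0.383 with an estimated correlation, of 12 endothelial genes 2 (9 adjusted over the list alone; camera adjusted p = 8.12e-05, adjusted p = 0.383 with an estimated correlation), and of 8 enteric nerve genes 1 (8 adjusted over the list alone; camera adjusted p = 0.000256, adjusted p = 0.383 with an estimated correlation). Within the arms, 8 of these 18 collagen and matrix genes fell and 2 rose in biopsies of the abx-titled arm, and 15 fell and 2 rose in the veh-titled arm (8 and 2, and 15 and 2, adjusted over the list alone; camera adjusted p = 0.822 and 0.056). Of the 12 endothelial genes, 5 fell and 3 rose in the abx-titled and 9 fell and 1 rose in the veh-titled arm (the same counts adjusted over the list alone; camera adjusted p = 0.702 and 0.308), so a higher effect here includes a smaller fall. In the shams alone, 13 of the 18 collagen and matrix genes were lower in the abx-titled arm. The effect differed for 392 genes (311 upward and 81 downward). The split was 222 and 247 after median of ratios scaling, 215 and 211 after quantile normalization and 174 and 85 when libraries were rescaled without small RNAs. The count moved with single libraries, to 237, 246 and 254 without abx-titled biopsy replicate 4, biopsy replicate 5 and sham replicate 4, and to 240, 694, 239, 252 and 253 without veh-titled biopsy replicates 1, 3 and 6 and sham replicates 1 and 6. It was 213 with the stricter filter, 1245 with array weights, 167 with a replicate block, 259 in all in the rescaling without small RNAs, and 578 (397 upward and 181 downward) without abx-titled sham replicates 2 and 5, chosen after seeing the data because they stood apart.

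The shams of both arms were then compared with each other. Cyp2c55, a cytochrome P450 of the colon, was lower in the abx-titled shams, at 21.5 ± 15.5 against 267 ± 117 FPKM (SD, n = 6 each), a log2 difference of -3.82 ± 0.43 (SE, adjusted p = 4.33e-06). The epithelial sodium channel subunits Scnn1b and Scnn1g were higher, Scnn1b at 32.8 ± 4.39 against 9.48 ± 1.23 FPKM (SD, n = 6 each, difference 1.69, adjusted p = 4.65e-08) and Scnn1g with a difference of 1.76. Also lower were Ppy, pancreatic polypeptide (-2.31), the drug transporters Abcb1a (-1.77) and Abcb1b (-1.46), which are close copies and uncertain, the carboxylesterase Ces2a (-1.77), the chloride channel regulator Clca6 (-1.53) and Car1, at 506 ± 340 against 1309 ± 169 FPKM (SD, n = 6 each). The acute phase protein Saa1 was higher, at 1196 ± 355 against 505 ± 106 FPKM (SD, n = 6 each, adjusted p = 0.000234), with Saa2 as a close copy, and so were Apol7a (1.23), Casp14 (1.22) and Il18bp (1.87), whose call some alternatives lost (adjusted p = 0.0129 to 0.125).

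Of 18 collagen and matrix genes, 13 were lower in the abx-titled shams (15 adjusted over the list alone), with Col3a1 at -1.21 and Col1a1 at -1.03. Collagen and matrix genes had a camera adjusted p = 5.22e-11 and an adjusted p = 0.832 with an estimated correlation. Of 16 colonocyte genes, 5 were lower (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0406, adjusted p = 0.85 with an estimated correlation). None of the 15 interferon-stimulated genes passed on its own, although the list did in camera (adjusted p = 0.00148, adjusted p = 0.85 with an estimated correlation), with Gbp2 at 1.58 (adjusted p = 0.179) and Ido1 at 1.40 (adjusted p = 0.254). The microbiota-induced epithelial genes rose in 2 of 14 members, Saa1 and Saa2 (0.88), with 2 adjusted over the list alone, a camera adjusted p = 0.0311 and an adjusted p = 0.85 with an estimated correlation. A total of 1490 genes differed (400 higher and 1090 lower in the abx-titled shams), with 602 and 802 after median of ratios scaling, 724 and 888 after quantile normalization, and 505 and 975 without abx-titled sham replicates 2 and 5, chosen after seeing the data. Of all these genes, 11 were higher and 28 lower by at least 1 on the log2 scale.

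Between the biopsies of both arms, Cyp2c55 was again lower in the abx-titled group, at 8.80 ± 4.36 (SD, n = 5) against 116 ± 37.4 FPKM (SD, n = 6), and Scnn1b higher, at 33.7 ± 5.83 (SD, n = 5) against 7.95 ± 2.07 (SD, n = 6), with log2 differences of -3.65 ± 0.45 (SE, adjusted p = 1.98e-05) and 1.97 ± 0.14 (SE, adjusted p = 1.99e-08). Ccl3 (-2.09), Hao2 (-2.01), Ces2a (-1.99), Ppy (-1.92), Car1 (-1.73), Cxcl2 (-1.55), Clps, colipase (-1.55), and the muscle enolase Eno3 (-1.53) were lower. The neuropeptide Gal (1.84), the bile acid binding protein Fabp6 (1.67), the antigen peptide transporter Tap1 (1.65), the immunoglobulin joining chain Igj (1.46), Scnn1g (1.27), Irf1 (1.17) and Id3 (1.12) were higher. Some alternatives lost the calls of Gal (adjusted p = 0.0103 to 0.0964), Fabp6 (0.000208 to 0.122) and Tap1 (0.00219 to 0.117). Of 20 cytokines and chemokines, 12 were lower and 1 higher (15 and 1 adjusted over the list alone). Cytokines and chemokines had a camera adjusted p = 6.41e-09 and an adjusted p = 0.287 with an estimated correlation. Of 14 sterol synthesis genes, 8 were lower (10 adjusted over the list alone; camera adjusted p = 3.2e-06, adjusted p = 0.517 with an estimated correlation), and of 7 squamous markers 6 (6 adjusted over the list alone; camera adjusted p = 5.47e-06, adjusted p = 0.0618 with an estimated correlation). Of 6 red blood cell genes, 5 were higher (5 adjusted over the list alone; camera adjusted p = 0.00218, adjusted p = 0.517 with an estimated correlation), and of 8 enteric nerve genes 3 (6 adjusted over the list alone; camera adjusted p = 0.00132, adjusted p = 0.578 with an estimated correlation). Of 18 collagen and matrix genes, 3 were lower and none higher (3 adjusted over the list alone), with a median log2 difference of -0.07, at a camera adjusted p = 0.119. A total of 1781 genes differed (926 higher and 855 lower), with 840 and 1244 after median of ratios scaling, and 3394 differed with array weights.

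**Figure D3:**
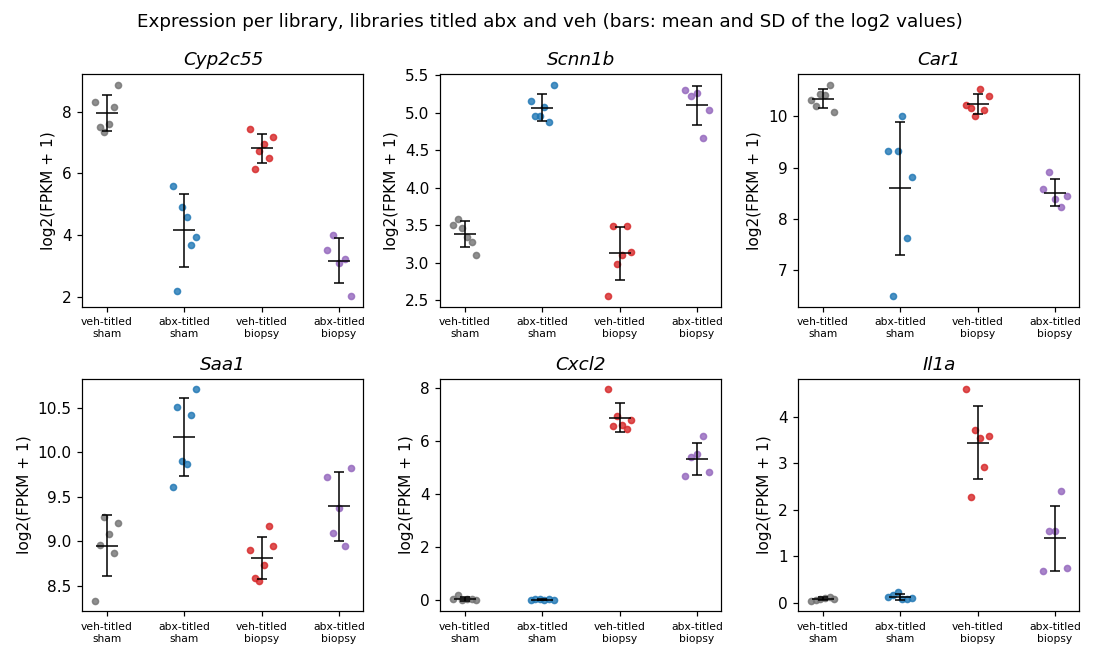
Each point is 1 library of the second cohort, the 4 groups are on the horizontal axis, the vertical axis is log2(FPKM + 1), and the bars are the mean and SD of the log2 values. Cyp2c55 and Car1 were lower and Scnn1b was higher in both groups of the abx-titled arm, while Cxcl2 and Il1a rose in the biopsies of both arms, to 42.1 and 1.88 FPKM in the abx-titled and 125 and 11.2 FPKM in the veh-titled arm.

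The response to biopsy at 6 h was measured in 3 sets of libraries that share none, the time course and both arms. Across the genes tested in both of each pair, which are not independent replicates, the correlation of log2 changes was 0.906 between the time course and the abx-titled arm and 0.904 between the time course and the veh-titled arm (11795 genes each), and 0.941 between the arms (11849 genes). The time course and the abx-titled arm shared 2435 higher genes, where independent lists would share 802, and 4419 lower, against 2269. With the veh-titled arm the shared genes were 2448 higher, against 775, and 4718 lower, against 2534. Between the arms they were 2593 higher, against 807, and 4783 lower, against 2552, with 25 and 4 in opposite directions. These counts, too, are from the main fits.

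Positions of some of the named genes are given in the mm10 build (GENCODE vM21). Fosl1 (ENSMUSG00000024912.6) lies on chromosome 19 from 5447547 to 5455946, S100a9 (ENSMUSG00000056071.12) on chromosome 3 from 90692632 to 90695721, Krt14 (ENSMUSG00000045545.8) on chromosome 11 from 100203162 to 100207548, and Spp1 (ENSMUSG00000029304.14) on chromosome 5 from 104435118 to 104441050. Rnf186 (ENSMUSG00000070661.6) lies on chromosome 4 from 138967112 to 138968360, Slc37a2 (ENSMUSG00000032122.15) on chromosome 9 from 37227585 to 37255738, Slc26a3 (ENSMUSG00000001225.12) on chromosome 12 from 31390871 to 31473917, and Col1a1 (ENSMUSG00000001506.10) on chromosome 11 from 94936224 to 94953042. Cyp2c55 (ENSMUSG00000025002.5) lies on chromosome 19 from 39007019 to 39042693, Scnn1b (ENSMUSG00000030873.9) on chromosome 7 from 121865038 to 121918514, and Il1a (ENSMUSG00000027399.1) on chromosome 2 from 129299610 to 129309972. Scnn1g (ENSMUSG00000000216.8) lies near Scnn1b on chromosome 7, from 121734479 to 121768475.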

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

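The test of T and NK cell genes and the comparisons with other splits of the libraries were planned before their results were seen, and all other tests of explanations in this part were chosen only after the result was seen.

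Interferon-stimulated genes were lower in biopsies than in shams at 6 d, with a median log2 change of -0.61. A raised level in the 6 d shams, in place of a fall in the biopsies, was asked about with the 14 shams of the other times. The 6 d biopsies lay 1.83 above these shams (median log2 difference, 16 of 16 genes higher), and the 6 d shams 2.06 above them. Both 6 d groups were thus raised. The values cannot decide, because a fall from a level raised in both groups would also leave the biopsies above those shams. Scaling of the libraries is argued against as the cause, since the median log2 change after quantile normalization was -0.71. More T and NK cells in the 6 d shams cannot be told apart from other sources, because the list of their markers differed by 0.46 between the 6 d shams and the other shams, between the bounds set for and against it. A time-dependent response of sham tissue stays open and was not tested, as the labels give no batch and each time has its own shams.

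The abx-titled and veh-titled shams differed in 1490 genes. That 2 abx-titled shams stand apart (replicates 2 and 5) is argued against as the whole cause, since 1480 genes were called without them. If the condition field has the arms exchanged, the abx-titled mice had the antibiotics. The untreated 6 h shams of the time course may then be expected to lie nearer the veh-titled ones. With the median offset between the cohorts removed, 69.6% of the called genes did (1034 of 1486). The share was 61.8% of those higher and 72.4% of those lower in the abx-titled shams, against 54.9% and 50.4% of the genes not called. Genes not called differ little between the arms, so their shares are a weak comparison. The time course is also another cohort, so this nearness goes with the explanation but cannot decide on it. If the title field has the arms exchanged, genes induced by microbes would be higher in the abx-titled shams, which cannot be told apart, since limma's fry gave that list a p of 0.0502. In camera the list was higher in the abx-titled shams at the preset correlation, but did not pass with an estimated correlation. Of its 14 tested members 2 were called, the close copies Saa1 and Saa2. Neither field is taken as right, and batch and animal differences between the cohorts stay open.

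Of 7 tested squamous epithelial markers, 4 rose in biopsies at 3 d and 3 at 6 d, and after median of ratios scaling or quantile normalization 2 rose and 1 fell at 6 d. Anal or skin tissue in the biopsies could bring all abundant squamous transcripts. Of 16 squamous markers, 3 rose at both times (Krt14, Krt13 and Krt15) and 9 were too low to be tested. Because only 7 markers could be called at all, the bound set against this explanation was met in advance. The count therefore cannot decide. The levels say more, as the 9 untested markers stayed under 1 FPKM in every biopsy of 3 d and 6 d. Krt5 reached at most 0.181, Krt1 0.0841 and Lor 0.835 FPKM, where Krt14 reached 98.3 FPKM. These low levels argue against anal or skin tissue as the source of Krt14, although Krt13 and Krt15 rose with it. That 1 or 2 libraries carry the rise is argued against, since 0 of the 11 biopsies had a mean over the 6 tested markers other than Krt14 at or below the highest of the 10 shams (lowest biopsy 1.10 and highest sham 0.69 on the log2 scale). Krt14 was left out because it was named for having no overlap. Krt13 stayed in that mean and weighs heavily in it, with means of 9.31 and 8.03 FPKM in the biopsies of 3 d and 6 d against 0.245 in the highest sham. The injury, which the design names, stays among the open explanations as a hypothesis and was not tested further.

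For each count, 1 of 100 splits of the libraries, the real one, gave as many genes, which argues against a random division of these libraries as the source. With 100 splits, no share under 1 in 100 can be seen. The splits treat libraries as interchangeable, so they cannot speak to differences between animals or batches, which the labels do not give. The real count and the highest of the other splits were 7219 and 5141 at 1 h, 8961 and 7234 at 6 h, 5666 and 5067 at 3 d, and 5875 and 2018 at 6 d. They were 6226 and 4388 for the difference between 1 h and 6 h, 6936 and 3176 between 6 h and 3 d, 244 and 70 between 3 d and 6 d, and 7835 and 2027 among the shams. In the arms they were 8350 and 7037 for the abx-titled and 8848 and 6428 for the veh-titled arm, 392 and 71 for the difference of effects, 1490 and 145 between shams, and 1781 and 567 between biopsies.

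A single library lay far from the others of its group for 13 of 81 sets of values tested. Chance would give about 1 in 20 if values followed a normal distribution, which need not hold for FPKM tested without a log. In all flagged sets but that of Retnlb, the library that stood apart was the highest. In the time course these were Sprr1a in sham 1 h replicate 1 (13.61 FPKM, nearest 5.32), Rnf186 in biopsy 1 h replicate 4 (19.24, nearest 8.546), Hba-a1 in biopsy 1 h replicate 5 (3306, nearest 1370), Krt6a in sham 6 h replicate 1 (0.054, nearest 0.01535) and Cxcl10 in sham 6 h replicate 4 (4.225, nearest 0.9049). Sham 3 d replicate 1 stood apart for Krt14 (1.71, nearest 1.341) and Slc26a3 (949.5, nearest 546.5), biopsy 3 d replicate 6 for Myh11 (108.6, nearest 54.28), biopsy 6 d replicate 3 for Retnlb (14.7, nearest 18.52) and sham 6 d replicate 1 for Dtx3l (34.86, nearest 25.98). In the arms these were Sprr1a in abx-titled sham replicate 5 (2.349, nearest 1.257) and Cxcl2 in veh-titled biopsy replicate 1 (246.9, nearest 121.3) and in veh-titled sham replicate 2 (0.144, nearest 0.03578).

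The effect of the biopsy differed between 1 h and 6 h for 6226 genes in limma, with Cxcl3 (4.967), Ccl4 (4.852), Ifit3 (4.729), Ifit1 (4.578) and Mmp3 (4.513) at one end and Arc (-3.923), Fosb (-3.477), Pck1 (-3.336), Slc37a2 (-2.95) and Atf3 (-2.764) at the other. Between 6 h and 3 d it differed for 6936 genes, with Clu (4.051), Retnlb (3.409), Klk15 (3.333), Col1a1 (3.093) and Nov (2.902), and with Krt6a (-5.705), Cxcl10 (-5.04), Sprr1a (-4.719), Ifit3 (-4.395) and Rsad2 (-4.356). Between 3 d and 6 d it differed for 244 genes, with C1qtnf3 (2.031), Fmod (2.008), Mal (1.35), Mfap4 (1.336) and Mdk (1.283), and with Oasl2 (-2.812), Ifit1 (-2.68), Isg15 (-2.584), Apol9a (-2.523) and Apol9b (-2.339); this count was 521 without sham 3 d replicate 1, 159 without sham 3 d replicate 2, 146 without biopsy 6 d replicate 2 and 155 without sham 6 d replicate 1. Between the arms it differed for 392 genes, with Id3 (1.156), Erbb3 (1.059), Col6a2 (0.99), Clca6 (0.979) and Igfbp3 (0.974), and with Il1a (-2.097), Ccl3 (-2.046), Cxcl2 (-1.522), Ccl4 (-1.442) and Csf3 (-1.333). That count was 237, 246 and 254 without abx-titled biopsy replicates 4 and 5 and sham replicate 4, and 240, 694, 239, 252 and 253 without veh-titled biopsy replicates 1, 3 and 6 and sham replicates 1 and 6.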

How the results depend on the processing

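Rescaling without small RNA symbols and leaving out libraries rich in B cell genes or abx-titled shams 2 and 5 were chosen after seeing the data, and the other alternatives were planned. Of 310 alternative counts over 13 comparisons, 288 were within 1.5 times the count reported. Many of these alternatives left out 1 library, and only totals were compared. The split into higher and lower genes is not covered by this, and in several comparisons it turned with scaling, as given with each. For the difference between 3 d and 6 d (244 genes) the counts beyond 1.5 times were 1006 with array weights, 161 with only the groups compared, 131 with a replicate block, and 146 to 521 when 1 library was left out. For the difference between the arms (392 genes) they were 213 with the stricter filter, 1245 with array weights, 167 with a replicate block, 259 rescaled without small RNA symbols and 237 to 694 with 1 library left out. With array weights 3394 genes differed between the arms' biopsies (1781 reported). The cause of these was not tested. With the stricter filter 5346 genes changed in the abx-titled and 5605 in the veh-titled arm (8350 and 8848 reported), since 7316 genes were tested in place of 11849. Krt19 reversed in the difference between 1 h and 6 h, from 0.38 to -0.085 after quantile normalization (adjusted p = 0.00304 to 0.707 over the alternatives), and the cause was not tested. The labels do not say whether a biopsy and a sham with equal replicate numbers came from 1 animal. Over 29 such pairs the correlation of their deviations from the group means was -0.282 to 0.254. In 5 of them the sham of the same number was the closest. Deviations in groups this small are uncertain, so these values cannot decide whether libraries were paired, and the main fits used no pairing. Of 1101 calls of named genes, 1036 were kept with median of ratios scaling, 1041 with quantile normalization, 1073 with a pseudocount of 0.1 and 961 in all leave-outs, and 904 of the 964 in the comparisons fitted with a replicate block. Of 355 gene list tests, 145 passed camera and 28 did with an estimated correlation, 177 passed fry and 138 passed after quantile normalization. Absolute depth is unknown, so for genes near the floor the changes are limited by it.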

Other observations

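Further gene lists are given here that the report does not describe. Mast cell proteases were higher in biopsies at 6 d, with 3 of 4 list members rising (3 adjusted over the list alone), Mcpt1 at 1.61 and Mcpt2 at 1.56 (camera adjusted p = 0.00365, adjusted p = 0.0659 with an estimated correlation). Of 11 complement genes, 8 rose at 3 d (8 adjusted over the list alone), led by C3, the central component (1.52), with a camera adjusted p = 0.0128 and an adjusted p = 0.515 with an estimated correlation. Of this list 1 rose and 5 fell at 1 h, 3 rose and 3 fell at 6 h, and 4 rose at 6 d. In each arm 1 of 10 tested members rose and 6 fell. At 6 h, 7 of 16 hypoxia and glycolysis genes rose and 1 fell (7 and 1 adjusted over the list alone), with Pfkfb3, a regulator of glycolysis, at 1.71 and the lactate transporter Slc16a3 at 1.57 (camera adjusted p = 0.00643, adjusted p = 0.404 with an estimated correlation). After median of ratios scaling 12 of them rose and 1 fell. At 1 h 5 of the list rose and 8 fell, at a camera adjusted p = 0.327. Of 12 Wnt and BMP niche genes, 9 fell at 1 h (9 adjusted over the list alone), among them Bmp4 (-0.94) and Wnt4 (-0.91), but the list did not pass camera (adjusted p = 0.327), the median shift of all genes was -0.18, and 7 fell after quantile normalization. At 3 d 6 of these genes rose and 1 fell, and at 6 d 4 rose and 1 fell (camera adjusted p = 0.468 and 0.918).

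The B cell gene Cd79a stood at 108.9 FPKM in biopsy 6 d replicate 3, 36.6 in sham 6 d replicate 2 and 25.9 in sham 1 h replicate 1, against at most 6.03 in the other time course libraries. In the arms it stood at 27.5 FPKM in abx-titled sham replicate 3, against at most 6.66 in the others. B2m, a subunit of MHC class I, was 1442 and 1312 FPKM in abx-titled shams 2 and 5, against at most 827 in the other libraries of the arms. These libraries and genes were chosen after their values were seen.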
